A study of Rattus norvegicus with 10 samples.

How the data were processed

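The study profiled kidney cortex RNA from Dahl salt-sensitive rats fed 4% NaCl for 3 weeks with 2% oxonic acid or with vehicle, 5 libraries per group. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was selected with poly-T beads, and libraries were made with random priming and sequenced on Illumina instruments; the protocol text covers both directional and non-directional libraries and does not say which was made. Per the submitters' processing notes, the tools named were fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3. The genome build and gene annotation are not given in the sources used here, so coordinates are those of the deposited table.

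The deposited table gave, per gene and library, FPKM values computed by the authors. Each FPKM multiplied by the gene length in the table was a whole multiple of a library constant (100% of values within 0.01 of a whole read), which returned the reads in genes, 14.5 to 18.5 M (mega) per library. The library size that the authors divided by was 0.977 to 1.04 times the summed reads, and the median ratio of each library to the geometric mean over 15629 genes was 1.00 in all 10 libraries, so the deposited FPKM already carry a median-ratio scaling. The ratio of the authors' library size to the summed reads was 0.992 ± 0.0116 (SD, n = 5) with oxonic acid and 1.02 ± 0.0154 (SD, n = 5) with vehicle (two-sided exact permutation test, p = 0.0238; adjusted p = 0.0992 over 5 library measures, which did not pass). Values were kept as the authors scaled them. Poly-A selection and FPKM measure relative abundance, so a change in a few abundant transcripts, such as those of mitochondria, shifts the share left for the others. FPKM does not weigh a value by its reads; 3 reads in a gene of median length were worth 0.0733 to 0.0959 FPKM, below the filter.

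Samples were grouped by the treatment label, and table columns were matched to samples by the library name in the description. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom between any pair being 4.79. Genes with a mean FPKM of at least 0.5 over the 10 libraries were tested (14508 of 32545, 13408 of them protein-coding) on log2(FPKM + 0.5) with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, oxonic acid against vehicle, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because of the pseudocount, fold changes of genes with low values are understated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

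The test, 41 gene lists and the rule for naming genes were fixed before the data were examined. Of 908 list symbols, 845 were matched to the table by exact symbol and 757 passed the filter; where several gene IDs shared a symbol, the one with the highest mean was used. The 38 lists with at least 5 measured members were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over the 38 lists, and again with an estimated correlation, with fry and, as an addition, with an exact permutation test of the list level per library (252 arrangements, smallest possible p 0.00794). The lists of B and plasma cell markers, neutrophil and mast cell markers and sex-linked transcripts had fewer than 5 members. The limma p-values of members were also adjusted over their own list alone, which was not part of the plan fixed in advance. That adjustment does not correct over the 38 lists, and members that vary together can pass together. A list's mean and level weigh its members equally. Of the 370 genes in the 19 called lists, 18 belong to 2 of them.

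Genes are named by 3 rules. The first takes the 12 genes with the largest change in each direction among those with an adjusted p under 0.05, a mean FPKM of at least 1 and at least 4 of 5 oxonic acid libraries beyond the vehicle median; since 0 genes passed, it was filled with the smallest unadjusted p in each direction under the same conditions, and those genes did not pass. Genes without a symbol, or whose symbol is a provisional locus name (starting with LOC, RGD, AABR, AC1, ENSRNO, NEWGENE or Rn), were skipped. The second takes up to 4 passing members of each list or, with none, the 2 with the smallest p. The third always takes a fixed set that includes Slc22a12, Slc2a9, Abcg2, Xdh, Havcr1, Lcn2, Spp1, Ccl2, Slc12a3, Nlrp3 and Xist; no value of Xist was used here. Some genes and a list that the rules select are left out of the text and figures. Of the 105 genes selected, 4 overlap another tested gene.

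The procedure was tested on simulated data with means and spread taken from these libraries and counting noise added (5 draws of 14508 genes with 200 genes changed). It called 50.4% of genes changed 1.5-fold, 77.9% of those changed 2-fold and 92.1% of those changed 4-fold, and 0.0573% of unchanged genes; camera with the preset correlation called, at an unadjusted p under 0.05, 5 of 5 lists of 30 genes moved 1.25-fold and 0 of 5 unmoved ones. The simulated genes were independent of each other, unlike genes in tissue. Counting noise entered the simulation 2 times, since the spread of the libraries already holds it, so the simulated spread need not equal theirs.

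Other settings fixed in advance were pseudocounts of 0.1 and 1, no filter or a mean FPKM of at least 1, median-ratio scaling, nuclear protein-coding genes rescaled to 1 total, robust empirical Bayes, array weights, voom on the recovered reads, the replicate number as a block, the run of sample numbers as a block, leaving out each library in turn, an adjusted p under 0.1, an estimated correlation and fry. Settings added after seeing the data were leaving out vehicle libraries 4 and 5, which had the lowest array weights (0.294 and 0.633), scaling to the summed reads in genes, the inner medulla or macrophage list level as a covariate, and the exact permutation of list levels. Blood pressure, plasma urate and histology were not analysed here.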

Results

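RNA from the kidney cortex of Dahl salt-sensitive rats was sequenced after 3 weeks on a diet with 4% NaCl, eaten alone or together with 2% oxonic acid. The Dahl salt-sensitive strain (SS/JrHsdMcwi) is an inbred rat line whose blood pressure climbs on a salty diet, and oxonic acid inhibits uricase, the enzyme that degrades uric acid in rodents. Before the switch the animals ate 0.4% NaCl, and their blood pressure was recorded by telemetry for 4 days. The data comprised 10 libraries, 5 from high salt with oxonic acid and 5 from high salt with vehicle. The labels number the libraries within each group without tying each one to its own rat. The p-values of single genes, fry and the exact permutation tests therefore measure the spread between these samples, part of which may be technical. Camera at the preset correlation instead compares a list's members with the other genes tested, so its p-value is not a measure of that spread. The deposited table gave FPKM (fragments per kilobase, scaled to library size) for 32545 genes, of which 14508 had a mean FPKM of at least 0.5 and were compared. Reads assigned to genes, computed back from FPKM and gene length, numbered 16.0 ± 1.62 M (M, mega; SD, n = 5) in the oxonic acid libraries and 16.4 ± 1.17 M (SD, n = 5) in the vehicle libraries, with a range of 14.5 to 18.5 M. At that depth 1 read in a gene of the median length of 2157 bp was worth 0.0244 to 0.0320 FPKM.

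The libraries differed in some ways beyond diet. Transcripts of the mitochondrial genome took 12.6% ± 0.773 (SD, n = 5) of the reads in genes in the oxonic acid libraries and 11.2% ± 1.14 (SD, n = 5) in the vehicle libraries, a difference with p = 0.0397 in a two-sided exact permutation test and adjusted p = 0.0992 over the 5 library measures compared. The lowest share, 9.23%, was in vehicle library 4, which also stood apart on the first principal component (18.2% of the variance), at 39.8 against -13.7 to 15.5 for the other 9. The design used rats of both sexes and the labels give no sex per sample. The Y-linked Eif2s3y ran from 34.6 to 48.7 FPKM and Ddx3y from 14.9 to 17.2 FPKM over all 10 libraries. With Kdm5d and Uty, these Y-linked genes were at 0.723 of their median or more in every library, which argues against a female library among the 10. The numbers in the sample descriptions fall into 3 runs: run A holds 3 oxonic acid and 0 vehicle libraries, run B holds 1 and 3, and run C holds 1 and 2. The labels do not call these runs batches.

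The comparison of high salt with oxonic acid against high salt alone asks which cortical transcripts go with uricase inhibition during salt loading. Genes of tubular injury, cell division, immune cells and matrix were lower as groups in the oxonic acid libraries, and markers of the distal nephron, with genes of sodium and potassium transport, were higher as groups. The tubular injury list fell by 0.44 on the log2 scale, a mean fold of 0.737, with 28 of its 30 measured members lower (adjusted p = 0.274 with an estimated correlation). Its best known member, Havcr1 (kidney injury molecule), measured 12.96 ± 6.93 FPKM (SD, n = 5) with oxonic acid and 28.2 ± 10.3 FPKM (SD, n = 5) with vehicle. The groups overlapped for Havcr1, and it did not pass (limma adjusted p = 0.396). Markers of collecting duct principal cells rose by 0.39 on the log2 scale, with 10 of 10 members higher (adjusted p = 0.274 with an estimated correlation), a call that ended with the sample-number runs as a block (camera adjusted p = 0.126), the difference within run C being -0.03. Of 38 gene lists tested with limma's camera at a preset inter-gene correlation of 0.01, 10 were lower and 9 higher at an adjusted p under 0.05. None of these 19 calls held with an estimated correlation, where the smallest adjusted p was 0.274, and limma's fry called 0 lists.

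**Figure D1:**
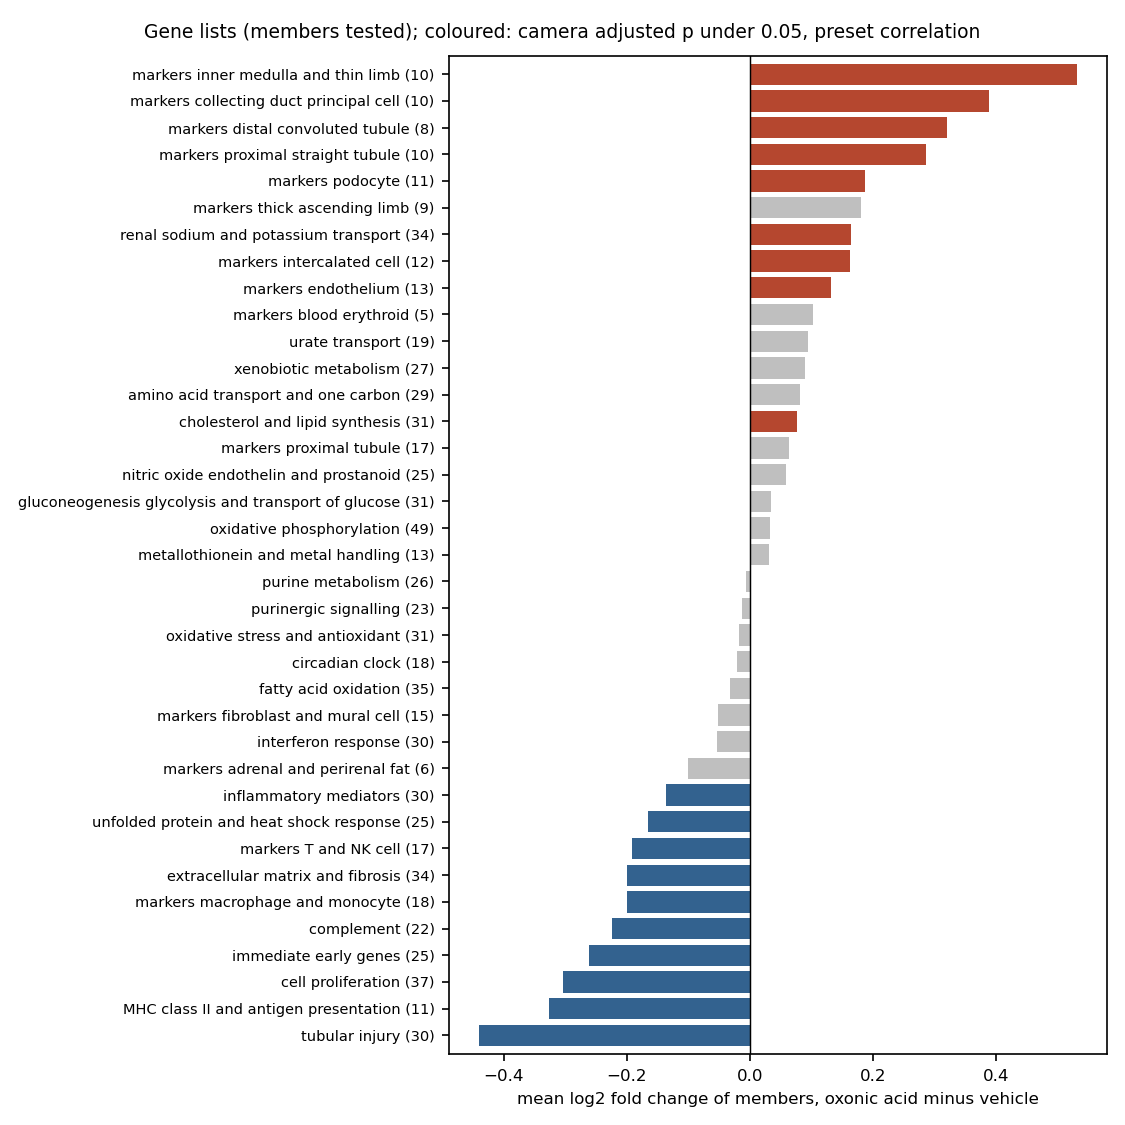
Mean log2 fold change of the members of each gene list shown, oxonic acid minus vehicle, on the horizontal axis, with the number of members tested beside each name. Coloured bars are the 10 lower and 9 higher lists called by camera with the preset correlation; the longest bars are tubular injury at -0.44 and inner medulla markers at 0.53.

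No single gene passed the threshold. In limma's test on log2(FPKM + 0.5), 0 genes were higher and 0 lower at an adjusted p under 0.05, whereas 1377 genes had an unadjusted p under 0.05 (627 higher, 750 lower), against 725.4 that chance would give. The voom variant of limma, run on the recovered reads, also called 0 genes, with 1414 at an unadjusted p under 0.05. In 277 genes (1.91%) the ranges of the groups did not overlap, against 0.794% by chance. The gene nearest to the threshold was Tap2 (ENSRNOG00000046031, chromosome 20, 5198258 to 5212624 in the coordinates of the deposited table, whose build is not given in the sources used here), a subunit of the transporter that loads peptides for MHC class I. Tap2 measured 4.95 ± 0.293 FPKM (SD, n = 5) with oxonic acid and 7.10 ± 0.182 FPKM (SD, n = 5) with vehicle, a log2 difference of -0.48 (SE 0.06, limma adjusted p = 0.0890), and it passed, with adjusted p = 0.0471, when limma weighted the libraries by their quality.

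The other genes given here for their small unadjusted p did not pass, with limma adjusted p of 0.327 to 0.333. Among those with higher values, Cacng5, a calcium channel gamma subunit, measured 49.5 ± 10.1 FPKM with oxonic acid and 24.3 ± 5.70 FPKM with vehicle (SD, n = 5 each). Tnfrsf11b (osteoprotegerin) measured 8.90 ± 1.36 and 5.11 ± 1.37 FPKM in the same order, and the elongase Elovl5 measured 52.9 ± 1.24 and 46.7 ± 1.04 FPKM. The oxysterol-binding protein genes Osbpl8 and Osbpl3 had log2 differences of 0.46 and 0.32, the retinoblastoma gene Rb1 0.29, Cpeb3 0.37, Inppl1 0.23 and the small heat shock gene Hspb6 0.23. The carboxylesterase Ces1d had a log2 difference of 0.47 but overlaps another tested gene of its family on the same strand, and U6, at 1.71, is 1 copy of a repeated small nuclear RNA, so both values are uncertain. Rb1 and Ns5atp9 each overlap a gene on the opposite strand, and the labels do not settle whether strand was used in counting.

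Among those with lower values, Ns5atp9, which encodes a PCNA-binding protein of dividing cells, measured 3.16 ± 0.976 FPKM with oxonic acid and 7.57 ± 2.20 FPKM with vehicle (SD, n = 5 each). Ubd, an interferon-responsive ubiquitin-like gene, measured 31.2 ± 8.67 and 63.9 ± 16.8 FPKM in the same order. The proto-oncogene Myc measured 6.88 ± 1.16 and 11.1 ± 1.61 FPKM, and the lysosomal protease gene Ctsl measured 1361 ± 56.7 and 1689.6 ± 101.9 FPKM. Log2 differences were -0.76 for Sectm1b, -0.58 for the actin-binding Tmsb10, -0.46 for Pla2g7, -0.45 for Tmem107, -0.44 for the complement receptor C5ar2, -0.38 for the lamin Lmnb1 and -0.33 for the tubulin Tubb5. In 23 of the 24 genes that led by unadjusted p, not all of them printed here, the libraries of the groups did not overlap. The exception was Sectm1b. Choosing genes by small p makes such separation likely, so it adds no support.

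**Figure D2:**
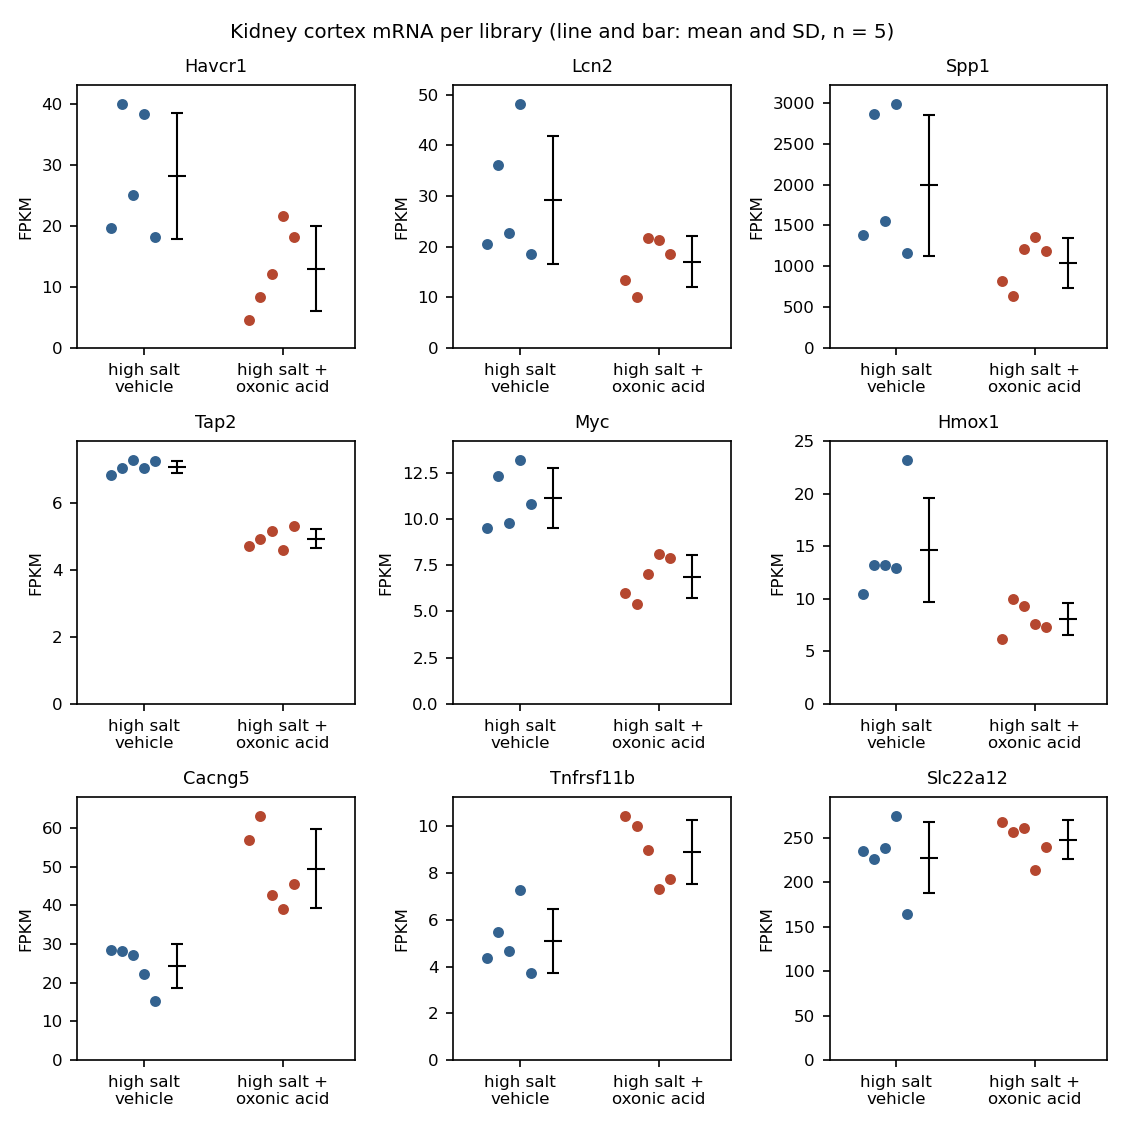
FPKM of 9 genes on the vertical axis, 1 point per library, for high salt with vehicle and high salt with oxonic acid; the line and bar beside the points are the mean and SD of 5 libraries. Tap2, Myc, Hmox1, Cacng5 and Tnfrsf11b show no overlap between groups, Havcr1, Lcn2 and Spp1 overlap, and the urate transporter Slc22a12 lies at 248 ± 21.6 against 228 ± 39.8 FPKM.

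Injury and cell cycle transcripts formed the lower groups with the smallest camera p at the preset correlation. At that setting other splits of the libraries into 5 and 5 called a median of 11 lists, so chance is not excluded. The exact permutation of list levels gave adjusted p of 0.101 for injury and 0.151 for proliferation. Of the tubular injury list, 0 of 30 members passed over all genes tested and 13 passed when adjusted over the list alone, all of them lower (camera adjusted p = 8.0e-13; adjusted p = 0.274 with an estimated correlation). Counts adjusted over a list alone, here and below, are not corrected over the lists, and members that vary together can pass together. The haem oxygenase gene Hmox1 measured 8.10 ± 1.54 FPKM with oxonic acid and 14.6 ± 4.94 FPKM with vehicle, and the protease inhibitor Timp1 17.6 ± 4.66 and 27.8 ± 4.65 FPKM (SD, n = 5 each). Lcn2 (neutrophil gelatinase-associated lipocalin) measured 17.0 ± 5.07 and 29.1 ± 12.7 FPKM, and Spp1 (osteopontin) 1044 ± 304 and 1989.9 ± 865.8 FPKM, with limma adjusted p of 0.481 and 0.414. All 37 cell proliferation genes were lower, by 0.30 on average on the log2 scale, 0 of them past the threshold over all genes and 11 when adjusted over the list alone (camera adjusted p = 2.6e-16; adjusted p = 0.274 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 measured 2.58 ± 0.767 and 4.76 ± 1.01 FPKM, and the replication clamp Pcna 44.8 ± 2.28 and 51.0 ± 2.19 FPKM. Within the sample-number runs B and C, the injury list differed by -0.27 and -0.39 and the proliferation list by -0.52 and -0.08. Vehicle library 4 had the highest injury level, 0.54, but a proliferation level of -0.11, and both lists kept their call without vehicle libraries 4 and 5, with camera adjusted p of 1.2e-10 and 3.7e-21.

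Stress-response transcripts were lower too. Immediate early genes fell by 0.26 on the log2 scale, with 21 of 25 members lower and 3 passing when adjusted over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.274 with an estimated correlation). Myc and the transcription factor Klf6, at 9.16 ± 1.39 FPKM with oxonic acid and 13.5 ± 1.88 FPKM with vehicle (SD, n = 5 each), led that list. Its call was lost without vehicle libraries 4 and 5, the libraries with its highest levels (camera adjusted p = 0.157). All 25 unfolded protein and heat shock genes were lower, by 0.17 on average, and 0 passed when adjusted over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.274 with an estimated correlation). Among them the endoplasmic reticulum genes Sdf2l1 and Pdia6 had log2 differences of -0.30 and -0.17.

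Lists of immune cells, immune mediators and matrix were lower as well. Macrophage and monocyte markers were lower by a mean of 0.20 on the log2 scale over the list, with 16 of 18 members lower. Of these, 5 passed when adjusted over the list alone (camera adjusted p = 2.6e-06, and 0.274 with an estimated correlation). The mannose receptor gene Mrc1 measured 1.13 ± 0.146 FPKM with oxonic acid and 1.91 ± 0.378 FPKM with vehicle, and the complement component C1qb 22.8 ± 2.92 and 29.7 ± 3.16 FPKM (SD, n = 5 each). MHC class II genes fell by 0.33 (median -0.20, 10 of 11 lower, camera adjusted p = 8.2e-05), inflammatory mediators by 0.14 (26 of 30, 8.2e-05), complement by 0.22 (19 of 22, 2.2e-04) and T and NK cell markers by 0.19 (13 of 17, 0.0059). For these 4 lists the adjusted p = 0.274 with an estimated correlation. In that order 0, 1, 1 and 1 members passed when adjusted over the list alone. Pycard, the inflammasome adaptor, measured 7.72 ± 0.859 and 10.9 ± 1.79 FPKM, Icam1 14.7 ± 1.37 and 17.3 ± 1.48 FPKM, and the T cell receptor component Cd3e 1.34 ± 0.447 and 2.35 ± 0.354 FPKM, while Cd28 went the other way at 3.85 ± 0.917 and 2.60 ± 0.656 FPKM. RT1-Da and RT1-DOa, from the rat MHC, had log2 differences of -0.22 and -0.49 and belong to a family of similar genes. The MHC class II mean was -0.19 without RT1-DMa and RT1-DMb, named after their values were seen. These had log2 differences of -0.73 and -1.15, and their vehicle values were 1.41 ± 1.499 and 3.77 ± 6.01 FPKM (SD, n = 5 each). The inflammasome gene Nlrp3 and the chemokine Ccl2 had log2 differences of -0.15 and -0.10, with limma adjusted p of 0.648 and 0.926. Extracellular matrix and fibrosis genes were lower by a mean of 0.20 over the list, with 30 of 34 members lower. Of these, 2 passed when adjusted over the list alone (camera adjusted p = 1.2e-06, and 0.375 with an estimated correlation). With the macrophage level as a covariate the matrix call ended, the mean going to -0.024 with 19 of 34 members lower (camera adjusted p = 0.657). The calls of inflammatory mediators (mean -0.066, adjusted p = 0.273), complement without the genes shared with the macrophage list (-0.21 to -0.13, 0.812) and T and NK cell markers (-0.19 to -0.16, 0.174) ended too. The last 2 kept most of their difference, and their median SE rose from 0.158 to 0.193 and from 0.172 to 0.234. T and NK cell markers had a camera adjusted p of 0.0514 without vehicle libraries 4 and 5.

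Markers of the distal nephron and transport genes were higher. Collecting duct principal cell markers (10 of 10 members higher) and the renal sodium and potassium transport list (28 of 34 higher, mean 0.16 on the log2 scale) had camera adjusted p of 2.6e-05 and 4.3e-05 (for both, adjusted p = 0.274 with an estimated correlation). Distal convoluted tubule markers were higher by a mean of 0.32 over the list, with 7 of 8 members higher and a camera adjusted p of 2.2e-04 (adjusted p = 0.274 with an estimated correlation). For these 3 lists the numbers passing when adjusted over the list alone were 0, 0 and 5. The water channel Aqp4 measured 2.86 ± 1.66 FPKM with oxonic acid and 1.09 ± 0.120 FPKM with vehicle, and the sodium channel subunit Scnn1g 14.5 ± 1.19 and 11.7 ± 1.83 FPKM (SD, n = 5 each). The kinase Stk39, which activates sodium chloride cotransport, measured 9.85 ± 1.03 and 7.68 ± 0.739 FPKM, the proximal sodium-proton exchanger Slc9a3 31.4 ± 2.37 and 25.5 ± 2.60 FPKM, and the magnesium channel Trpm6 4.39 ± 0.267 and 3.35 ± 0.397 FPKM. The thiazide-sensitive cotransporter Slc12a3 itself measured 100.4 ± 14.5 and 92.0 ± 25.9 FPKM (limma adjusted p = 0.787). Inner medulla and thin limb markers were higher as well, by 0.53 (9 of 10 members, camera adjusted p = 0.0275; adjusted p = 0.528 with an estimated correlation), and oxonic acid library 3 carried the highest level of that list, 1.55. Within the sample-number runs B and C, the collecting duct list differed by 0.31 and -0.03, the transport list by 0.22 and 0.15, and the distal convoluted tubule list by 0.27 and 0.40. With the runs as a block the collecting duct call ended (camera adjusted p = 0.126), whereas the transport and distal convoluted tubule calls stood at 3.2e-05 and 0.00228. With the macrophage level as a covariate those 2 calls ended (camera adjusted p of 0.108 and 0.174). The transport mean went from 0.16 to 0.14 while its median SE rose from 0.120 to 0.143, and the distal convoluted tubule mean went from 0.32 to 0.17.

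**Figure D3:**
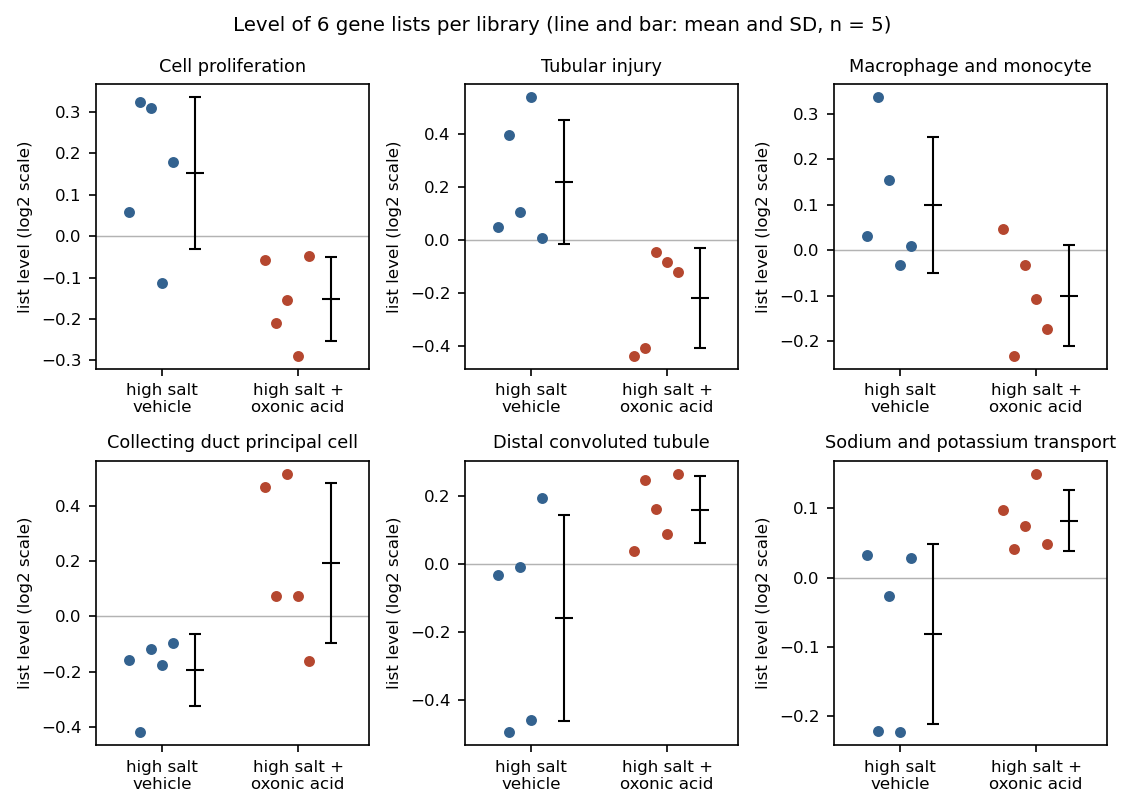
Level of 6 gene lists per library on the log2 scale (mean over members of log2(FPKM + 0.5) minus the mean of all 10 libraries), 1 point per library, with the mean and SD of each group of 5. The oxonic acid libraries all lie below 0 for injury and proliferation and all above 0 for sodium and potassium transport, while the collecting duct level of oxonic acid library 5, at -0.16, lies among the vehicle libraries.

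The remaining higher lists covered other cell types and lipid synthesis. Podocyte markers rose by 0.19 (10 of 11 members, camera adjusted p = 0.0021; adjusted p = 0.399 with an estimated correlation), with Synpo at 15.3 ± 1.93 and 12.5 ± 2.44 FPKM (SD, n = 5 each). Intercalated cell markers rose by 0.16 (10 of 12, camera adjusted p = 0.00534; adjusted p = 0.457 with an estimated correlation), with Aqp6 at 70.0 ± 7.93 and 55.9 ± 8.03 FPKM; without vehicle library 2 that adjusted p was 0.242. Endothelial markers rose by 0.13 (11 of 13, camera adjusted p = 0.0105; adjusted p = 0.457 with an estimated correlation), with Kdr at 11.9 ± 0.906 and 9.48 ± 1.88 FPKM; without vehicle library 4 the adjusted p was 0.133. The endothelial call was also lost without oxonic acid library 3, and with the sample-number runs as a block the median turned from 0.12 to -0.015. Cholesterol and lipid synthesis genes rose by 0.08 (20 of 31, camera adjusted p = 0.0105; adjusted p = 0.274 with an estimated correlation), with Lss at 5.96 ± 0.465 and 5.03 ± 0.308 FPKM; without vehicle library 1 the adjusted p was 0.0535. Proximal straight tubule markers rose by 0.29 (7 of 10, camera adjusted p = 0.0475; adjusted p = 0.528 with an estimated correlation); without vehicle library 5, whose level was -1.07, the adjusted p was 0.469. Without vehicle libraries 4 and 5 the median turned from 0.20 to -0.012, and the straight tubule call held in 6 of the 10 fits that left out 1 library. The inner medulla call held in 5 of those 10 and had an adjusted p of 0.703 without oxonic acid library 3. With the macrophage level as a covariate the podocyte call ended (camera adjusted p = 0.174) with its median going from 0.23 to 0.19, and the intercalated cell list turned from a median of 0.12 to -0.083 (0.579). No member of these lists passed when adjusted over the list alone. With the sample-number runs as a block, 3 of the 9 higher lists and 10 of the 10 lower lists kept their camera call.

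Genes of urate handling and purine breakdown did not pass as groups. The urate transport list had 14 of 19 members higher and a mean log2 difference of 0.10 (camera adjusted p = 0.0803; adjusted p = 0.274 with an estimated correlation), and 0 members passed when adjusted over the list alone. The reabsorptive urate exchanger Slc22a12 measured 248 ± 21.6 FPKM with oxonic acid and 228 ± 39.8 FPKM with vehicle (SD, n = 5 each; limma adjusted p = 0.726). Slc2a9 measured 7.08 ± 0.662 and 6.92 ± 0.529 FPKM, Abcg2 64.2 ± 3.69 and 60.7 ± 5.41 FPKM, and Slc17a1 39.0 ± 5.58 and 32.0 ± 3.31 FPKM, with limma adjusted p of 0.922, 0.699 and 0.481. Xdh, whose product makes uric acid, measured 43.5 ± 7.44 and 48.4 ± 6.65 FPKM (limma adjusted p = 0.689). Purine metabolism had a camera adjusted p of 0.535, with a median log2 difference of 0.01 and a mean of -0.01. The mineralocorticoid receptor gene Nr3c2 measured 5.71 ± 0.481 and 4.67 ± 0.956 FPKM (limma adjusted p = 0.516). The lists of nitric oxide, endothelin and prostanoid genes (camera adjusted p = 0.469), oxidative stress (0.842), fatty acid oxidation (0.463), oxidative phosphorylation (0.535), proximal tubule markers (0.0803), thick ascending limb markers (0.0638) and fibroblast and mural cell markers (0.189) did not pass either. In the oxidative stress list the median was 0.00 and the mean -0.02 on the log2 scale, and Ncf1 measured 6.18 ± 0.801 and 7.68 ± 0.578 FPKM. In the epithelial lists Egf measured 38.8 ± 6.39 and 28.2 ± 4.77 FPKM and Aqp1 674 ± 64.1 and 558 ± 55.6 FPKM.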

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

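No test in this part was chosen after its result was seen. In each group of 5 libraries, the highest or lowest value was singled out when its gap to the nearest other library exceeded 0.71 of the group's range (Dixon's test), over 4 library measures, the gene list levels and the genes named. Of 300 groups tested, 15 had such a library, and chance alone gives about 1 in 20, or 15.

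Among vehicle libraries, library 4 had a mitochondrial share of 9.23%, the lowest, against 11.3% in the nearest. Library 2 had the lowest collecting duct principal cell level, -0.42 on the log2 scale, the highest Ctsl value, 1868 FPKM, and the highest Cyp1b1 value, 2.40 FPKM. Library 5 had the lowest proximal straight tubule level, -1.07, with Slc7a13, an amino acid transporter of that segment, at 245 FPKM against 746 FPKM in the nearest library; it also had the highest Hmox1 (23.2 FPKM) and Cd28 (3.74 FPKM). Library 1 had the highest purine metabolism level, 0.20.

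Among oxonic acid libraries, library 1 had the highest oxidative stress level, 0.041, and library 3 the highest purinergic signalling level, 0.052, and the highest Trpm6 value, 4.86 FPKM. Library 2 had the highest Rb1 value, 14.2 FPKM. Library 4 had the lowest Slc17a1 value, 29.2 FPKM, and the lowest Srebf2 value, 13.5 FPKM.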

How the results depend on the processing

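Leaving out vehicle libraries 4 and 5, scaling to summed reads, the inner medulla and macrophage covariates and the exact permutation of list levels were chosen after the results were seen. The count of genes past the threshold was 0 in every planned or added fit except 1 with array weights (Tap2), 1 at an adjusted p under 0.1 (Tap2) and, leaving out 1 library at a time, 0 to 1 (the small nucleolar RNA SNORA3 without vehicle library 1, fewer samples). The 19 list calls became 0 with an estimated correlation, with directional fry and with mixed fry (smallest mixed adjusted p 0.0547). They also became 0 with the exact permutation of list levels (9 lists under 0.05 unadjusted, smallest adjusted p 0.101). The estimated correlation lay above the preset 0.01 in all 19, from 0.0726 (cholesterol and lipid synthesis) to 0.642 (distal convoluted tubule markers). It was 0.263 for injury and 0.374 for proliferation, so members varied together more than the preset assumes. That argues against taking the preset camera p at face value. Why fry and the permutation called 0 was not tested, and the smallest p that permutation can give, 0.00794, limits its adjusted p over 38 lists. Elsewhere 14 (macrophage covariate) to 25 lists were called, 17 to 25 leaving out 1 library. Among lists called in either fit, camera's direction reversed for inner medulla markers with the inner medulla level as covariate (median 0.083, fixed by that covariate), for interferon response (0.17), proximal tubule (-0.13) and intercalated cell markers (-0.083) with the macrophage level as covariate, and for fatty acid oxidation leaving out 1 library (-0.091 to 0.038). In all, 17 lists had a median of the other sign in some fit, 3 of them called: intercalated cell, endothelial (-0.015 with the sample-number runs as a block) and proximal straight tubule markers (-0.012 without vehicle libraries 4 and 5). The cause was not tested. Of 105 named genes, 7 changed sign in some fit. Median-ratio scaling moved nothing, since the deposited values carry it, and says nothing about stability. The Xist covariate was not run. Depth limits genes near the filter: 3 reads in a gene of median length are up to 0.0959 FPKM.

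With the replicate number as a block, 0 genes and 23 lists (13 higher, 10 lower) were called, and 1445 genes had an unadjusted p under 0.05. The numbers do not pair the libraries: same-numbered libraries deviated together with r of -0.01 to 0.20, over 0.1 in 1 of 5 pairs, and 1 of 5 oxonic acid libraries correlated best with its own number.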

Other observations

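Of the tests in this part, those with the macrophage or inner medulla level as a covariate, the count of splits for genes at an adjusted p under 0.05, the count of lower lists with the runs as a block, the shift of the median gene between scalings and the comparison of Y-linked genes were chosen only after the list results were seen.

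Several lists outside transport, injury and immunity moved little. In metallothionein and metal handling, 7 of 13 members were higher and 6 lower (camera adjusted p = 0.498), yet 3 passed when adjusted over the list alone; Trpm6 and the magnesium transporter regulator Cnnm2 had log2 differences of 0.35 each, and ceruloplasmin (Cp), named after its values were seen, had -0.34. In glucose metabolism and transport (camera adjusted p = 0.187), 1 member passed when adjusted over the list alone, the glucose transporter Slc2a2, at 49.8 ± 7.39 FPKM with oxonic acid and 65.9 ± 3.84 FPKM with vehicle (SD, n = 5 each), and Ldha measured 182 ± 12.2 and 215 ± 27.1 FPKM. In xenobiotic metabolism (camera adjusted p = 0.0803), 1 member passed when adjusted over the list alone, Ces1d, whose family members overlap, and Cyp1b1 had a log2 difference of -0.57. Amino acid transport and one-carbon genes were higher in 21 of 29 members (camera adjusted p = 0.0803), with the betaine and GABA family transporter Slc6a13 at 25.8 ± 1.95 and 21.6 ± 1.86 FPKM.

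The interferon list had 17 of 30 members lower (camera adjusted p = 0.105), with Ifi27 at 163 ± 8.42 FPKM with oxonic acid and 193 ± 15.7 FPKM with vehicle and the immunoproteasome gene Psmb9 at 13.7 ± 1.22 and 17.3 ± 2.77 FPKM (SD, n = 5 each). Circadian clock genes went both ways (camera adjusted p = 0.898), with Nr1d1 and Nfil3 at log2 differences of 0.29 and -0.45. Purinergic signalling genes had a median of 0.01 and a mean of -0.01 (camera adjusted p = 0.945), with Nt5e at 0.20 and P2ry6 at -0.21. Erythroid markers (camera adjusted p = 0.469) and adrenal and perirenal fat markers (0.548) did not pass; Slc4a1, shared by erythrocytes and intercalated cells, had a log2 difference of 0.44 and Bpgm -0.02, and Adipoq and Cyp11a1 had 0.28 and -0.28. Of lists too short to test, B and plasma cell markers had 3 of 3 members lower (Fcrla -0.44, Ighm -0.10), neutrophil and mast cell markers 1 of 3 (Mmp9 -0.09, Kit 0.13) and sex-linked transcripts 2 of 4 (Eif2s3y -0.11, Ddx3y 0.07).

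The excess of genes with small unadjusted p was compared with other groupings of the same libraries. Of 100 splits into 5 and 5, drawn from 126 with the real split included, 2 gave as many genes at an unadjusted p under 0.05. The real split was among them, with 1377 genes against at most 1385 in another split. Such a count was rare among the splits, but chance is not excluded, since 1 other split gave more. The splits also exchanged libraries across the sample-number runs, while run A holds oxonic acid libraries only, so they do not separate diet from run. The split with 1385 exchanged oxonic acid library 4 and vehicle library 5. For genes at an adjusted p under 0.05 the count was 0 and all 100 splits gave as many, the highest other split giving 6, so chance cannot be excluded there either.

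For the lower injury, proliferation and immune lists, 7 of the 100 splits, the real one among them, called as many lists (19, with a highest other of 20 and a median of 11), and 6 called as many of the 10 lower lists in 1 direction (10, with a highest other of 10), so chance cannot be excluded. The 10 lower lists were taken from the real split, which therefore has the highest count possible in the second comparison. Vehicle library 4 alone is argued against, since 10 of the 10 lower lists stayed called without it, though at the preset correlation, at which other splits also called lists. The sample-number runs stay open. With the runs as a block 10 of the 10 stayed called, and 10 of 10 had the same sign within run B and within run C. But run A holds no vehicle library, and runs B and C hold 1 oxonic acid library each, which all these lists share. Some differences there were small, such as -0.045 for immediate early genes in run B and -0.036 for matrix in run C. The authors' scaling with the mitochondrial share is argued against, since other scalings shifted the median gene by -0.031 at most, against -0.14 for the smallest difference among the lower lists. Rats of different sex in the groups are argued against too, since 4 Y-linked genes were at 0.723 of their median or more in all 10 libraries. Less leukocyte RNA in the oxonic acid libraries is argued against as the whole cause for the injury list, whose 27 members outside the immune lists differed by -0.45 with the macrophage level as a covariate and -0.48 without (median SE 0.232 and 0.181; camera adjusted p = 3.2e-07, preset correlation). With that covariate the matrix difference shrank from -0.20 to -0.024 (median SE 0.157 and 0.192). The inflammatory one shrank from -0.14 to -0.066 (median SE 0.119 and 0.153). Less leukocyte RNA predicts both drops. They show only that these lists followed the macrophage level over the libraries, not where their RNA came from. The complement difference went from -0.21 to -0.13 (median SE 0.158 and 0.193). It kept over 0.5 of its size and lost its call as the SE rose, which leaves less leukocyte RNA open there. The T and NK cell difference went from -0.19 to -0.16 (median SE 0.172 and 0.234) and lost its call in the same way. Those markers are leukocyte transcripts themselves. The covariate asks only whether they follow macrophages, so it cannot test less leukocyte RNA for them. The same covariate also took the mean of the distal convoluted tubule markers from 0.32 to 0.17, so it may track more than leukocyte RNA. The smaller differences with it therefore cannot be assigned to leukocyte RNA alone. A response of the kidney to the diet stays open and untested.

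The higher collecting duct and distal convoluted tubule lists were weighed against medulla in the dissected cortex. With the inner medulla level as a covariate, the 9 collecting duct members outside that list differed by 0.23 instead of 0.33 (camera adjusted p = 0.00159), and the distal convoluted tubule list by 0.37 instead of 0.32 (camera adjusted p = 1.3e-04), both at the preset correlation. Inner medulla, as far as that list measures it, thus did not account for the whole of either difference, although it may carry part of the collecting duct one. The list is a weak measure of medulla. Its level varied widely with oxonic acid (SD 0.881, against 0.314 with vehicle), and it holds low members such as Slc14a2, at 0.121 FPKM with vehicle. More medulla that the list does not track therefore stays open. With the macrophage level as a covariate the distal convoluted tubule mean went from 0.32 to 0.17 (median SE 0.150 and 0.187) and the sodium and potassium transport mean from 0.16 to 0.14 (median SE 0.120 and 0.143), and both calls ended (camera adjusted p of 0.174 and 0.108). The sample-number runs B and C, in which the collecting duct list differed by 0.31 and -0.03, stay open for that list.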
